A study of Mus musculus with 6 samples.

How the data were processed

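RNA from full thickness mouse skin wounds, taken 8 days after injury, was measured on 6 single-colour Illumina bead arrays, 1 array per sample. The probe table deposited by the authors gives the average bead signal of each probe as an intensity on a linear scale, without normalization between arrays, together with a detection p-value for each probe and array, per the file headers. Software for scanning and bead summarization is not given in the sources used here. A second table deposited by the authors holds log2 values of the same arrays. R 2.14 and limma are named in the submitters' processing notes, with no settings. Each log2 column ranked the probes of its own array as the intensities did (Spearman correlation 1), the column medians lay at 5.12, and the values differed by at most 0.0916 from those computed here, so the scale is log2 and the direction is that of the intensities. How the authors set background and offset is not given in the sources used here. No array slide or scan day was given, so a batch could not be tested. No sample column of either table was left out.

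The probe table held 45281 probes and 2 further lines with no value. Of these probes, 34885 had 1 gene in the platform annotation and 18 had several, while 10378 were not listed there and are unnamed here, which does not mean that they match no gene. Symbols were updated through Entrez numbers against RefSeq genes of the mouse assembly GRCm38.p6, where 34807 probes matched. That assembly was used for names and for which genes are neighbours, and no coordinates were taken from it. No probe sequences were used.

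Values were computed from the intensities with limma 3.58.1 in R 4.3.3. Background was corrected by the normal-exponential model with the detection p-values (neqc), an offset of 16 was added, log2 was taken, and the 6 arrays were quantile-normalized together. Quantile normalization gives all arrays the same distribution, so a change in the same direction in most genes would be removed. The offset shrinks the differences of dim probes. A probe was kept if its detection p-value was under 0.01 on at least 2 of the 6 arrays (17410 probes), or on at least 1 of the 2 arrays for the adenovirus pair (17590 probes). Each gene was represented by the probe with the highest mean over the 6 arrays, which left 10266 genes for the tests and 10233 for the pair. More than 1 probe passed for 3562 genes.

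Groups were taken from the sample titles. The labels call the samples biological replicates, and the precision is limited by their number, 2 arrays in each tamoxifen group and 1 in each adenovirus group. The knockdown was compared with its control by limma's lmFit and eBayes over the means of all 4 groups, so the spread came from the tamoxifen groups alone (2 residual degrees of freedom and 2.92 from the prior). Tests were two-sided, with Benjamini-Hochberg adjustment over all genes. The adenovirus arrays, 1 against 1, were compared without a test. There the number of genes at least 2-fold apart was counted. A trend was fitted over all 6 arrays with the level of β-catenin coded as -1 in the knockdown, 0 in both controls and 1 in the stabilized wound, and with the model system as a term. Gene lists, 28 in number, were fixed before the data were examined. In the knockdown, 26 lists with at least 5 measured genes were tested with camera at a preset correlation between genes of 0.01, with an estimated correlation beside it. In the pair, the median of each list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. For probes not detected on any array of one group, "at least" folds set the mean of the bright group against, on each array of the dim group, the higher of the lowest detected signal and the probe's own signal.

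Named genes followed a rule also set before the data were examined. The rule takes Ctnnb1. In the knockdown it takes 12 genes in each direction, filled with those of the smallest unadjusted p at a log2 change of at least 1 where too few passed. In the pair it takes the 12 genes in each direction with the largest differences among those detected on both arrays, and up to 4 in each direction detected on 1 array. In the trend it takes 6 genes in each direction. Of each list it takes up to 4 members, or any Wnt target. Probes without exactly 1 gene and clone names were not named.

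The steps were tested on simulated data with the real gene means, variances drawn from the fitted prior and 50 changed genes of each of 4 sizes, over 10266 genes. An earlier version, which drew from the moderated variances, called more unchanged genes and was replaced. In the simulated knockdown comparison 0% of the genes changed 1.5-fold were recovered, 20% of those changed 2-fold, 86% of those changed 4-fold and 98% of those changed 8-fold, with 3 unchanged genes called. In the simulated trend the same shares were 8%, 70%, 96% and 100%, with 2 unchanged genes called. There the simulated changes were equal and opposite in the knockdown and the stabilized array, as the coding assumes. The shares do not hold for genes that change otherwise. In the simulated pair, 58% of the genes changed 2-fold and 100% of those changed 4-fold were at least 2-fold apart, and so were 230 unchanged genes. Of 2 simulated lists of 15 genes shifted by 0.3 and 0.6, camera called both with the preset correlation and 0 with the estimated one, and 1 of 24 unshifted lists was called with the preset correlation. Genes were simulated independently of each other, whereas the correlation estimated for the measured skeletal muscle genes was 0.917. The simulation therefore does not check the preset correlation for lists whose genes move together. Alternatives covered background, offset, normalization, the authors' log2 values, the detection filter, the choice of probe, a replicate block, separate normalization of the 2 model systems, the prior, other list tests, other fold thresholds, and leaving out each array.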

Results

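Gene expression was measured in full thickness wounds of the mouse back skin 8 days after injury, when new tissue is being laid down, after β-catenin had been raised or lowered following the injury. β-catenin, encoded by Ctnnb1, joins cell contacts and carries the signal of the Wnt pathway into the nucleus. In the first model, mice of 2 months with loxP sites around exon 3 of Ctnnb1 received an adenovirus with Cre recombinase, which yields a stabilized β-catenin, or an adenovirus with green fluorescent protein (GFP) as the control, with 1 array each. In the second model, tamoxifen was given to mice with loxP sites around exons 2 to 6, either without Cre (tamoxifen control, 2 arrays, 4 months) or with a tamoxifen-inducible Cre (knockdown, 2 arrays, 5 months). Age therefore went with genotype in the second model. Between 15883 and 16681 of the 45281 probes were detected on an array, and the median intensity lay between 129.4 and 140.9. The GFP array had the fewest detected probes and the lowest mean intensity, 544.4 against 648.7 to 714.8 on the others. The 2 knockdown arrays correlated across genes with r = 0.99 and the 2 tamoxifen controls with r = 0.98, while the stabilized and GFP arrays had r = 0.9605. Tamoxifen control replicate 2 was closer to knockdown replicate 1 (r = 0.9812, with 230 genes at least 2-fold apart) than to its own replicate (r = 0.9764, with 295). Both adenovirus arrays were closer to tamoxifen control replicate 1 (r = 0.9633 for the GFP and 0.9648 for the stabilized array) than to each other.

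The brightest probe of Ctnnb1 stood at nearly the same level on all arrays. This probe, 1 of 4, read 11.77 and 12.07 (log2) in the tamoxifen controls and 11.73 and 11.84 in the knockdown, a difference of -0.13 ± 0.16 (SE; limma, adjusted p = 0.805). It read 11.56 on the GFP array and 11.49 on the stabilized array. The other 3 probes differed by 0.18, -0.24 and 0.05 in the knockdown and, in the same order, by -0.81, -0.03 and -0.69 in the stabilized array. Where these probes lie relative to the removed exons was not analysed here, and a probe outside them checks nothing.

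Canonical Wnt target genes did not pass in the knockdown with all arrays, and lay among random lists in the stabilized array. In the knockdown 12 of 17 measured targets were higher and 5 lower, with a median log2 difference of 0.18 (camera, adjusted p = 0.313, and adjusted p = 0.829 with an estimated correlation), which stood at percentile 98.98 of random lists. Their median was 0.48 without tamoxifen control replicate 2 and 0.40 without knockdown replicate 2, past the threshold (adjusted p = 0.0177 and 0.0281), but 0.05 without tamoxifen control replicate 1 and 0.0076 without knockdown replicate 1 (adjusted p = 0.64 and 0.809). Axin2, a feedback inhibitor of the pathway, differed by 0.34 ± 0.16 (SE), Nkd1 by 0.72 ± 0.37, Ccnd1 by 0.05 ± 0.17 and Lgr5 by 0.18 ± 0.52. The smallest unadjusted p belonged to Tnfrsf19, at 0.86 ± 0.27 (limma, adjusted p = 0.38), and Cd44, at -0.51 ± 0.19 (adjusted p = 0.443). In the stabilized array 8 of 16 targets were higher and 8 lower than in the GFP array. Their median difference of 0.02 stood at percentile 41.3 of random lists, with Axin2 at 0.21, Myc at 0.58, Ccnd1 at 0.47 and Bmp4 at -0.85.

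Knockdown wounds had more RNA of skeletal muscle, lymphocytes, mast cells, antigen presentation and Schwann cells, and less of wound edge keratinocytes, than tamoxifen control wounds. All 26 measured skeletal muscle genes were higher in the knockdown, by a median log2 difference of 1.36. Among them were Pvalb, a calcium buffer of fast fibres (1.52 ± 0.18, SE), Casq1, which stores calcium in the sarcoplasmic reticulum (1.30 ± 0.16), the perinatal myosin Myh8 (1.55 ± 0.23) and the calcium channel Ryr1 (1.48 ± 0.24). Of 17 basal and wound edge keratinocyte genes 15 were lower, with a median of -0.77, and those with the smallest p were the wound keratin Krt6a (-1.66 ± 0.20), the integrins Itga6 (-0.79 ± 0.13) and Itgb4 (-0.70 ± 0.14) and the cornified envelope precursor Sprr1b (-1.20 ± 0.23). These list shifts passed camera with the preset correlation, at adjusted p = 6.93e-22 for muscle and 1.62e-09 for keratinocytes. Neither held with an estimated correlation (adjusted p = 0.58 for muscle and adjusted p = 0.482 for keratinocytes). Over all genes limma passed 0 members of either list, with 25 muscle genes and 10 keratinocyte genes at an unadjusted p under 0.05, and adjusted over the list alone 25 and 10 passed.

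All 8 T and B cell markers were higher in the knockdown (median 0.77), among them the T cell receptor chains Cd3g (1.18 ± 0.13), Cd3d (1.10 ± 0.15) and Cd3e (0.76 ± 0.13) and the B cell receptor chain Cd79b (1.13 ± 0.18). Antigen presentation genes were higher in 9 of 10 cases (median 0.60), including Cd207 of Langerhans cells (0.65 ± 0.13) and the class II genes H2-Ab1 (0.73 ± 0.19), H2-Aa (0.59 ± 0.17) and H2-Eb1 (0.73 ± 0.22). Mast cell markers were higher in 7 of 8 cases (median 0.44), among them the proteases Cpa3 (0.87 ± 0.13), Cma1 (0.67 ± 0.15) and Mcpt4 (0.61 ± 0.14) and the IgE receptor chain Fcer1a (0.79 ± 0.14). All 8 Schwann cell and nerve genes were higher (median 0.54), among them the transcription factor Sox10 (1.59 ± 0.25), Ngfr (1.18 ± 0.36) and the myelin genes Mbp (1.56 ± 0.44) and Mag (0.73 ± 0.18). These 4 lists passed camera at adjusted p = 9.31e-06, 2.07e-05, 0.000809 and 0.000809, in that order. With an estimated correlation none did, at adjusted p = 0.482, 0.593, 0.58 and 0.536. Adjusted over the list alone, 4 T and B cell markers, 1 antigen presentation gene, 4 mast cell markers and 4 Schwann cell genes passed, against 0 over all genes in limma, where 5, 6, 4 and 5 had an unadjusted p under 0.05. Without tamoxifen control replicate 2 the medians of antigen presentation and mast cell genes were 0.38 and 0.69, and without tamoxifen control replicate 1 they were 0.79 and 0.31. Sebaceous gland genes were higher in 8 of 9 cases (median 0.57; camera, adjusted p = 0.0436, and adjusted p = 0.673 with an estimated correlation), with Pparg at 0.76 ± 0.24 and Scd1 at 0.69 ± 0.43, and 0 members passed over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05. Without tamoxifen control replicate 2 the sebaceous median was 0.91, without knockdown replicate 2 it was 0.21 (adjusted p = 0.509) and without tamoxifen control replicate 1 it was 0.09 (adjusted p = 0.891).

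Genes of inflammation, interferon response and matrix breakdown were lower in the knockdown. Proliferation (cell cycle) genes were lower on average, but their medians on single arrays overlapped between the groups. Relative to the mean of all arrays, these medians were 0.365 and -0.207 in the tamoxifen controls and 0.0466 and -0.53 in the knockdown. On the same scale, cytokine medians were 0.111 and -0.143 in the controls and -0.498 and -0.151 in the knockdown. Interferon medians were -0.522 and -0.132, against -0.571 and -0.912. In both lists a control array thus lay close to a knockdown array. Without knockdown replicate 1 the median difference of the cytokine list was -0.26. Interferon response genes were lower in 18 of 20 cases (median -0.45; camera, adjusted p = 5.95e-05, and adjusted p = 0.58 with an estimated correlation), with the GTPase Irgm1 at -0.52 ± 0.13 and Oasl2 at -0.53 ± 0.15, whereas the chemokine Cxcl9 was at 0.55 ± 0.15. Without tamoxifen control replicate 2 the interferon median was -0.21 (adjusted p = 0.0353). Inflammatory cytokines and chemokines were lower in 17 of 22 cases (median -0.32; adjusted p = 0.000601, and adjusted p = 0.536 with an estimated correlation), among them the neutrophil chemokine Cxcl1 (-0.67 ± 0.14), Il1a (-1.08 ± 0.28) and Tnf (-0.39 ± 0.15). Ccl3 (-0.47 ± 0.17) was read by a probe of the set with one shared profile described with the single genes. All 23 cell cycle genes were lower (median -0.39; adjusted p = 0.000183, and adjusted p = 0.673 with an estimated correlation), although 0 had an unadjusted p under 0.05, with Cdk1 at -0.63 ± 0.30 and Pcna at -0.53 ± 0.30. The cell cycle median was -0.65 without knockdown replicate 1 and -0.60 without tamoxifen control replicate 2, but -0.04 without tamoxifen control replicate 1 and -0.07 without knockdown replicate 2, and the call was lost both times (adjusted p = 0.389 and 0.182). Matrix proteases and their inhibitors were lower in 11 of 16 cases (median -0.24; adjusted p = 0.0176, and adjusted p = 0.536 with an estimated correlation), among them the collagenase Mmp13 (-0.94 ± 0.23), Adamts1 (-0.50 ± 0.13) and Plat (-0.59 ± 0.21). Without tamoxifen control replicate 1 their median was -0.15 (adjusted p = 0.0591). In these 4 lists limma passed 0 members over all genes and 0 adjusted over the list alone, and at an unadjusted p under 0.05 the interferon list had 5 lower and 1 higher, the cytokines 3, the cell cycle genes 0 and the proteases 3.

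Hair follicle and hair shaft genes were lower in 14 of 15 cases (median -1.63; camera, adjusted p = 0.00052, and adjusted p = 0.673 with an estimated correlation). The list median relative to the 6-array mean was 2.76 in tamoxifen control replicate 2 and -0.38 in replicate 1, against 0.40 and -0.90 in the knockdown. Without that control replicate the median difference was 0.23 (adjusted p = 0.289). Of its members, Sprr1a, a cornified envelope gene also used outside hair, was at -1.35 ± 0.13 and was the 1 member past the threshold adjusted over the list alone, while the inner root sheath keratins Krt28 and Krt71 were at -2.11 ± 1.20 and -1.92 ± 1.20.

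The other lists gave no call in the knockdown with all arrays. Fibrillar collagen and matrix genes had a median of -0.09 (camera, adjusted p = 0.115), with Thbs1 at -1.03 ± 0.14 and elastin, Eln, at 0.67 ± 0.22. Fibroblast markers had a median of -0.13 (adjusted p = 0.164), with Dpp4 at -0.75 ± 0.16. Myofibroblast and smooth muscle genes had a median of 0.02 (adjusted p = 0.562). Among them Acta2, the actin of myofibroblasts, was at -0.44 ± 0.13, whereas Des and Tpm2, which skeletal muscle also uses, were at 1.45 ± 0.31 and 1.21 ± 0.29. Macrophage markers had a median of 0.03 (adjusted p = 0.887), neutrophil markers of -0.02 (0.229), endothelial markers of -0.13 (0.313), differentiated epidermis genes of -0.08 (0.0503), adipocyte genes of 0.60 (0.0503), Wnt ligands and regulators of -0.10 (0.48), TGF-β pathway genes of 0.07 (0.802), adhesion and migration receptors of -0.12 (0.184), angiogenesis factors of -0.05 (0.131) and stress genes of 0.08 (0.938), each with its adjusted p from camera in parentheses. Leaving out 1 array brought some of these past the threshold. Adipocyte genes were at 1.18 without knockdown replicate 1 (adjusted p = 2.32e-07), at 0.64 without tamoxifen control replicate 2 (0.0353) and at -0.06 without knockdown replicate 2 (0.57). Without tamoxifen control replicate 1, differentiated epidermis genes were at -0.37 (2.45e-05), neutrophil markers at -0.23 (0.01) and stress genes at -0.24 (0.00616), and without control replicate 2 stress genes were at 0.34 (0.00885), fibroblast markers at -0.32 (0.0321) and macrophage markers at -0.20 (0.0375). Matrix genes were at -0.29 without knockdown replicate 1 (0.000445). Erythrocyte genes had 4 measured members and sex-linked genes 1, which was Xist, and these were not tested (medians -0.36 and 0.22). In several of the lists with no call some members passed when adjusted over the list alone, among them 4 myofibroblast genes and 2 Wnt ligands and regulators. The latter were Wnt6 (0.86 ± 0.14) and Rspo3 (0.81 ± 0.14), both higher although the list median was below 0.

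Gene by gene, 0 of 10266 genes passed in the knockdown (limma, smallest adjusted p = 0.16). At an unadjusted p under 0.05 there were 1093 genes, 641 higher and 452 lower, where chance alone gives 513, and 314 genes were at least 2-fold apart. Among the genes named by rule, none of which passed, those higher included the T cell chemokine Ccl5 (1.33 ± 0.13, SE), the lymphoid chemokine Ccl21a (1.45 ± 0.17), the natural killer cell receptor Klra3 (1.37 ± 0.16), the muscle chaperone Itgb1bp2 (1.93 ± 0.23), the epidermal keratin Krt2 (2.39 ± 0.29), Egfl8 (1.39 ± 0.17) and Entpd4 (1.05 ± 0.12). Gldn and Art5 were not detected in the tamoxifen controls and were higher by at least 1.10 and 0.91 (log2). S100a7a, an antimicrobial protein of stressed epidermis, the carbonic anhydrase Car2 and Slc4a1, the anion exchanger of red cells, were not detected in the knockdown and were at least 4.70-fold, 2.65-fold and 2.64-fold lower. The epithelial genes Gjb2, a gap junction protein, and Sfn were lower by -1.69 ± 0.22 and -1.16 ± 0.13. Zxda (-1.73 ± 0.18), Erich5 (-1.58 ± 0.18), Hsd3b2 (-1.11 ± 0.14) and Srr (-1.18 ± 0.15) were also lower, as was Ern2, by at least 1.35-fold, but their probes belong to a set with one shared profile over the arrays. Other probes of Srr were at -1.13, in the same set, and at 0.36, outside it, and another probe of Hsd3b2 was at -0.88. The groups did not overlap in 43.6% of genes, where chance gives 33.3%. The 2 other ways to split the 4 tamoxifen arrays gave 392 and 229 genes at an unadjusted p under 0.05, and with 3 splits no exact permutation could reach a one-sided p below 0.167.

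**Figure D1:**
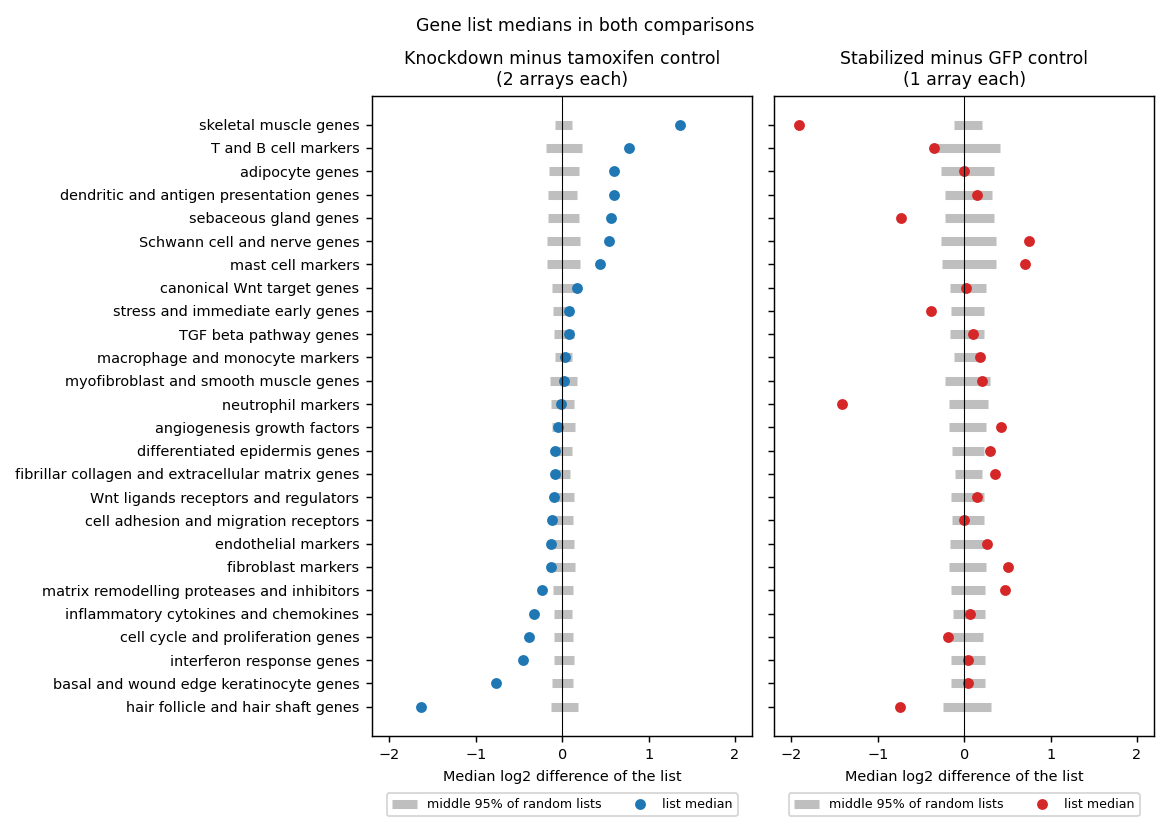
Median log2 difference (x axis) of 26 gene lists (rows) in the knockdown against the tamoxifen control (left) and in the stabilized against the GFP control array (right); points are list medians and grey bars the middle 95% of 10000 random lists of the same size. Skeletal muscle genes lie at 1.36 on the left and -1.91 on the right, while canonical Wnt target genes lie at 0.18 and 0.02.

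The wound with stabilized β-catenin had less RNA of skeletal muscle, neutrophils, hair and sebaceous glands, and more of fibroblasts, matrix, Schwann cells and mast cells, than the GFP control wound. With 1 array in each group there was no replicate check, and the percentiles describe these 2 arrays. All 25 measured skeletal muscle genes were lower, 24 of them at least 2-fold, with a median log2 difference of -1.91 that lay below all random lists (percentile 0). Pvalb was 7.36-fold lower, the muscle creatine kinase Ckm 7.35-fold and myoglobin, Mb, 6.04-fold, and Mybpc2, not detected on the stabilized array, was at least 9.32-fold lower. Neutrophil markers were at least 2-fold lower in 9 of 14 cases (median -1.41, percentile 0), including lactoferrin, Ltf (5.88-fold), Trem1 (4.68-fold), the chemokine Cxcl2 (4.65-fold) and Csf3r (3.98-fold). Relative to the 6-array mean the neutrophil median was 0.93 on the GFP array and -0.28 on the stabilized array, while the tamoxifen and knockdown arrays lay between -0.26 and 0.10.

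Fibroblast markers had a median of 0.51 (percentile 99.99), with Dpp4 2.39-fold and Ddr2 2.01-fold higher, and fibrillar collagen and matrix genes were higher in 23 of 27 cases (median 0.36, percentile 99.99), with fibronectin, Fn1, 2.17-fold, Lum 1.95-fold and Col1a1 1.63-fold higher. Matrix proteases and inhibitors had a median of 0.47 (percentile 99.95), with Adamts1 2.81-fold higher and the urokinase receptor Plaur 3.49-fold lower. Schwann cell genes had a median of 0.75 (percentile 100), with Ngfr 2.40-fold and Sox10 2.31-fold higher. Mast cell markers had a median of 0.70 (percentile 99.97), with Mcpt4 1.83-fold higher but Hdc 3.60-fold lower. Angiogenesis factors (median 0.43, percentile 99.94), differentiated epidermis genes (0.29, percentile 99.6) and endothelial markers (0.27, percentile 98.5) were higher, among them Vegfd (2.68-fold), Hbegf (2.49-fold) and Vwf (1.90-fold). Hair genes were lower in 11 of 11 cases (median -0.74, percentile 0), and sebaceous genes in 6 of 8 (median -0.74, percentile 0.01), with Fa2h 3.53-fold, Cidea 3.23-fold and Scd1 2.52-fold lower. Stress and immediate early genes (median -0.39, percentile 0; Gadd45b 4.53-fold and Atf3 3.31-fold lower), T and B cell markers (median -0.35, percentile 2.08, with 0 members at least 2-fold lower and Cd79b 2.04-fold higher) and cell cycle genes (median -0.19, percentile 0.64) were lower, but after a median shift in place of quantile normalization these 3 medians were above 0, at 0.13, 0.23 and 0.38. That scaling moved the median of all genes from 0.04 to 0.58.

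The medians of 12 of the 27 lists compared lay within the middle 95% of random lists. Among them were the Wnt targets, Wnt ligands and regulators (0.15, percentile 88.8), myofibroblast genes (0.21, percentile 90.6), macrophage markers (0.18, percentile 94.3), antigen presentation (0.15, percentile 77.2), wound edge keratinocytes (0.04, percentile 50.9), adipocytes (-0.0052, percentile 37.7), TGF-β pathway genes (0.11, percentile 77.2), inflammatory cytokines (0.07, percentile 56.3), interferon response (0.04, percentile 48.2), adhesion receptors (-0.00076, percentile 33.2) and erythrocyte genes (-0.71, percentile 3.71). Within the cytokine list members went both ways, with Tnf 6.74-fold and Osm 3.28-fold lower and Nos2, not detected on the GFP array, at least 3.76-fold higher. Macrophage markers did too, with Clec7a 5.35-fold and Cd14 3.09-fold lower and Retnla, a product of alternatively activated macrophages, 4.66-fold higher. Xist was the 1 sex-linked gene measured, at 0.43.

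Of 10233 genes, 874 were at least 2-fold apart between the 2 arrays, 362 higher and 512 lower in the stabilized wound. After a median shift in place of quantile normalization there were 1518 higher and 299 lower, and with no background correction 98 higher and 248 lower. The genes named by rule as higher began with Fcer1g, the shared signalling chain of IgE and IgG receptors (67.1-fold), and the interferon-inducible Ifi205 (45.1-fold), both of which were dim on the GFP array alone of the 6, as were Adh1, Inmt and Fgfr1op2, whose values follow. The hyaluronan synthase Has1 (5.98-fold), the ferritin receptor Scara5 (5.77-fold), Adh1 (4.52-fold), Cd209f (4.52-fold), the myelin gene Mbp (4.01-fold), Ces2g (3.90-fold), Ugt1a6b (3.86-fold) and Plekhb1 (3.66-fold) followed. Other probes of Mbp were at 0.30 and 1.5 (log2). Kif23 was 4.36-fold higher by its brightest probe, but its other probes were at -0.27 and -0.37 (log2). Genes lower in the stabilized wound included Acod1, which makes itaconate in activated macrophages (10.8-fold), the neutrophil chemokine receptor Cxcr1 (9.39-fold), the muscle ribosomal protein Rpl3l (7.68-fold) and Fam71f2 (7.40-fold). Ifngr2 was 10.1-fold lower by its brightest probe, while its other probes were at -0.06 and -0.14. Probes of the shared profile named above were also lower, for Zxda (44.1-fold), Erich5 (33.0-fold), Prf1 (28.8-fold), Rhbdl2 (18.5-fold), Ccdc144b (17.4-fold), Srr (14.3-fold) and Hsd3b2 (10.3-fold). Of genes detected on 1 array, Fgfr1op2, Inmt and Efhd1 were at least 8.92-fold, 8.68-fold and 5.73-fold higher in the stabilized wound, and Adal, Pisd-ps2 and Enah at least 14.0-fold, 11.5-fold and 8.77-fold lower. Another probe of Fgfr1op2 was at 0.43 (log2) and of Inmt at 2.82. The last 3 belong to the same set of probes, and other probes of Enah were at -0.0072 and of Adal at 0.03 and 0.71.

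**Figure D2:**
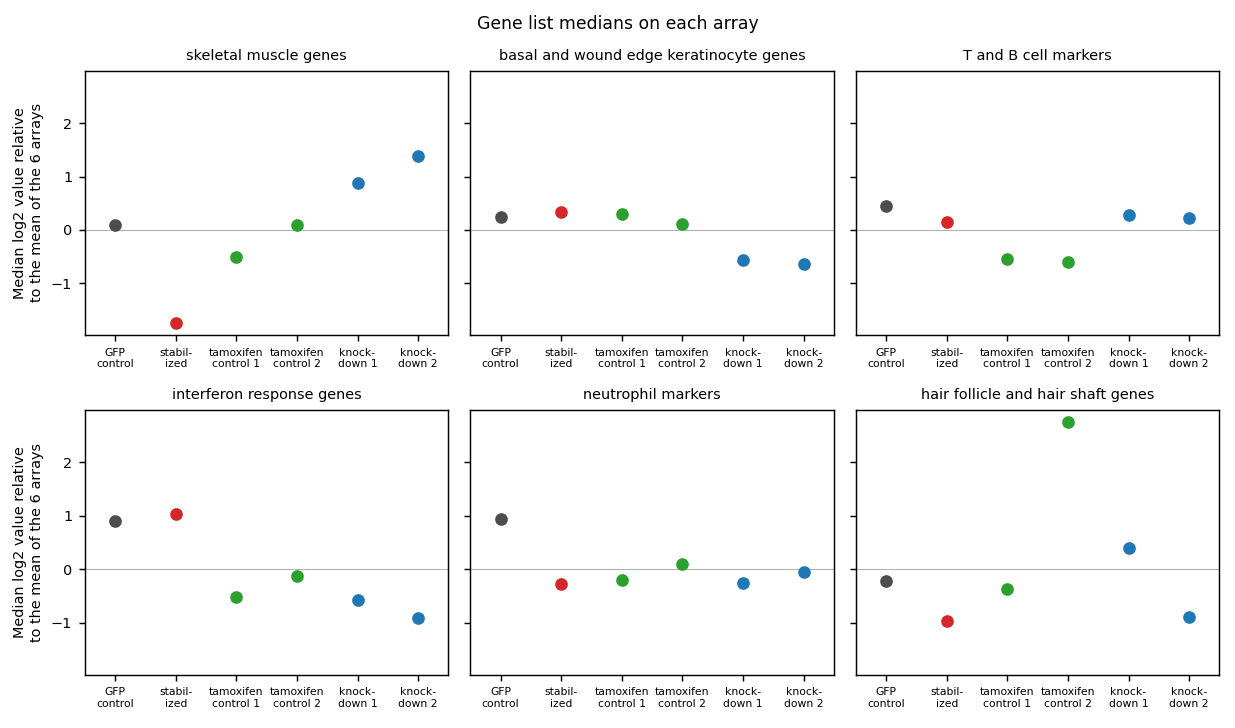
Median log2 value of 6 gene lists on each of the 6 arrays, relative to the mean of the 6 arrays (y axis); each point is 1 array, with colours for the 4 groups. Skeletal muscle genes range from -1.75 on the stabilized array to 1.39 on a knockdown array, and hair genes stand at 2.76 on 1 tamoxifen control array.

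**Figure D3:**
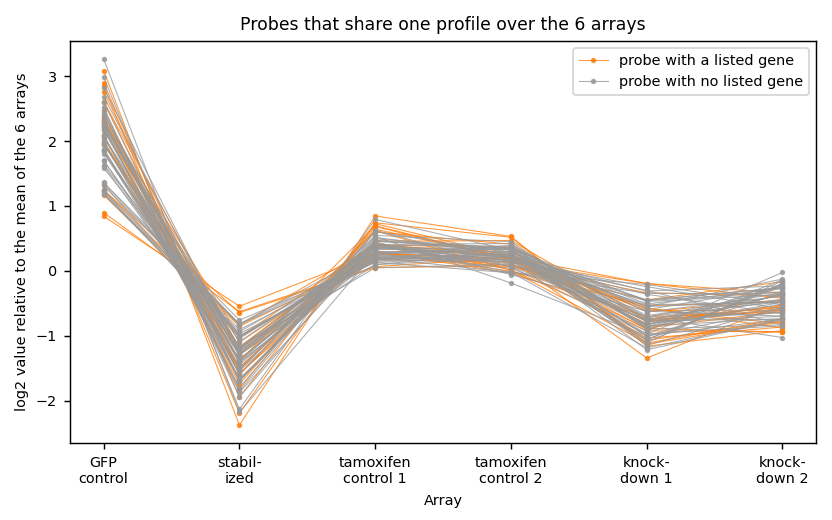
Log2 value relative to the mean of the 6 arrays (y axis) of the 72 probes that share one profile, on each array (x axis); each line is 1 probe, coloured by whether it has a listed gene. Their mean lies at 2.04 on the GFP array, at -1.35 on the stabilized array, at 0.36 and 0.21 on the tamoxifen controls and at -0.75 and -0.52 in the knockdown.

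In the trend over the coded level of β-catenin, skeletal muscle genes ran against the level in both models, although no single gene passed. The muscle genes Itgb1bp2 (-2.06 ± 0.19 per level, SE) and Trim72 (-1.27 ± 0.14), the chemokine Ccl21a (-1.33 ± 0.15) and Oas1d (-1.06 ± 0.12) were among the 6 genes of smallest p with a negative slope. Among the 6 with a positive slope were the growth factor Hbegf (1.08 ± 0.13), Fxyd4 (1.06 ± 0.14), the cornified envelope gene Cnfn (0.93 ± 0.12), the ceramide synthase Cers3 (0.78 ± 0.11) and the epidermal transcription factor Grhl3 (0.88 ± 0.13). Casq1 and Hhatl, with a negative slope, and Tmem255a, with a positive one, completed the 12, but were not detected on the stabilized array, on the stabilized array and both tamoxifen controls, and on the GFP array and in the knockdown, in that order, so no slope is given. In the knockdown Hhatl was at least 2.66-fold higher and Tmem255a at least 1.87-fold lower. All 12 had adjusted p = 0.124 in limma, and 0 of 10266 genes passed, with 1090 at an unadjusted p under 0.05. After the median shift in place of quantile normalization 186 genes passed. Among lists, skeletal muscle (camera, adjusted p = 1.4e-30, and adjusted p = 0.636 with an estimated correlation) and wound edge keratinocytes (adjusted p = 3.88e-05, and adjusted p = 0.665 with an estimated correlation) moved in opposite directions, with medians of -1.53 and 0.52 per level. T and B cell markers (median -0.53, adjusted p = 0.000181, and adjusted p = 0.636 with an estimated correlation), sebaceous genes (-0.50, 0.00782) and antigen presentation genes (-0.34, 0.00782) ran against the level, while interferon response genes (0.32, 0.00754), matrix genes (0.19, 0.00782), angiogenesis factors (0.13, 0.0117), proteases (0.31, 0.0154), fibroblast markers (0.25, 0.0281) and endothelial markers (0.20, 0.0304) ran with it, and with an estimated correlation their adjusted p lay between 0.636 and 0.692. In the stabilized array wound edge keratinocyte, interferon response and antigen presentation genes lay among random lists (medians 0.04, 0.04 and 0.15), so their slopes came from the knockdown, where angiogenesis factors in turn lay among random lists.

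The changes of the 2 models, which share no array, were weakly opposed across genes (Pearson r = -0.18, Spearman rho = -0.15, over genes, which are not independent replicates). The 2 other ways to split the 4 tamoxifen arrays into pairs gave r = -0.25 and r = 0.07, so the real split did not stand out. Without tamoxifen control replicate 1, r was -0.06.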

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

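The tests of explanations in this part, and those of the difference between the models, were chosen after the results had been seen.

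In 4 gene lists both knockdown arrays lay beyond both tamoxifen controls in one direction while the stabilized wound differed from the GFP control in the other direction, outside the middle 95% of random lists. The stabilized medians were -1.91 for skeletal muscle genes, -0.348 for T and B cell markers, 0.467 for matrix proteases and inhibitors and 0.43 for angiogenesis growth factors, against 1.36, 0.77, -0.238 and -0.0539 in the knockdown. The lists were chosen for their opposite medians, so a test of the difference between the models on the same values largely restates that choice. It passed camera with the preset correlation (adjusted p = 4.89e-25, 0.00347, 0.0213 and 0.00583), and did not with an estimated correlation (adjusted p = 0.696, 0.683, 0.683 and 0.683). Gene by gene, limma called 0 interactions, with 1586 genes at an unadjusted p under 0.05. For angiogenesis factors the knockdown median lay among random lists (percentile 14.99) and was above 0 without tamoxifen control replicate 1 (0.03) and without knockdown replicate 2 (0.08), so an opposed change is not shown there. In the T and B cell list the B cell chain Cd79b was higher in the stabilized wound too, by 1.03. The list median turned to 0.23 in the stabilized array after the median shift, where the median of all genes was 0.58. Among the other lists called in the knockdown, some moved the same way in both models and some did not. Mast cell and Schwann cell genes were higher in both, with medians of 0.438 and 0.536 in the knockdown and 0.702 and 0.75 in the stabilized array. Hair and cell cycle genes were lower in both (-1.63 and -0.385, then -0.742 and -0.187), although their knockdown calls were lost without single arrays. The cell cycle median in the stabilized array turned to 0.38 after the median shift. Sebaceous genes went opposite ways (0.568, then -0.737), but their medians on single tamoxifen control and knockdown arrays overlapped. Wound edge keratinocyte, interferon response, cytokine and antigen presentation genes lay among random lists in the stabilized array.

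For skeletal muscle, a different amount of muscle in the tissue taken is a candidate explanation. All 26 genes, which no other list holds, also differed in one direction between the 2 tamoxifen controls, which had the same treatment, by a median of 0.537, and all 26 did between the 2 knockdown arrays, by 0.563, both above all random lists. These differences within a group are smaller than the 1.36 between knockdown and control, and Pvalb read 12.51 and 12.83 in the controls, 14.08 and 14.29 in the knockdown, 13.26 on the GFP array and 10.38 on the stabilized array. A response that follows the level of β-catenin, with a median of -1.53 per coded level, cannot be told apart from it, because the stabilized level rests on 1 array and muscle content was not measured apart from expression. Age, which differed between knockdown and control, also stays open and was not tested.

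Among the 2354 detected probes with no listed gene, which no comparison above used, 437 were at least 2-fold apart between the stabilized and GFP arrays, 331 lower and 106 higher. That is 18.6% of them, against 8.54% of the named genes. The first share counts every probe and the other counts genes, each by its brightest probe, so the units differ. Of 49 such probes at least 8-fold lower in the stabilized wound, 32 belonged to the set of probes with one shared profile.

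That set was found by starting from 5 of the genes with the largest differences (Zxda, Erich5, Prf1, Rhbdl2 and Srr) and taking every detected probe with a correlation above 0.97 and a slope above 0.3 to their mean profile, and it held 72 probes for 24 named genes, brightest on the GFP array, lower in both knockdown arrays and lowest on the stabilized array. For the 11 genes with further detected probes, taken as a set, a change in their transcripts is argued against by all 17 of these, in the set or not, with a median stabilized minus GFP difference of 0.0688 and 3 below -1 (1 each of Srr, Hsd3b2 and Clec4e), but it stays open for Hsd3b2 and Clec4e (median -2.75) and for 13 genes with no further probe, among them Zxda, Erich5, Prf1 and Rhbdl2. A response that follows the level of β-catenin is argued against by the 87 probes at least 8-fold lower on the stabilized than on the GFP array, a choice that used no tamoxifen array and that shares 52 probes with the set, since 83 of them were lower in the knockdown as well, with a median of -0.939. A shared or repeated sequence read by these probes, with a level that differs between animals, may account for the profile and stays open. Of the probes in the set 34.7% had a listed gene, against 87.3% of all detected probes. Fisher's exact test against the remaining detected probes gave p = 2.84e-25 (two-sided). It takes probes as independent, which those chosen for one profile are not, so this p is no measure of chance. No probe sequences were used, so the low share does not decide the question.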

How the results depend on the processing

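The alternatives named as added below were chosen after seeing the data. The count of genes passing in the knockdown stayed at 0 in 16 of 17 alternatives with limma (smallest adjusted p from 0.0203 to 0.869), and leaving out 1 array gave 0 to 3. The 3 genes, named after their values were seen, were the hair genes Krt33a, Krt86 and Krtap7-1, and they passed without tamoxifen control replicate 1, which leaves control replicate 2 alone. There the lone array is assumed to vary like the other group. The trend count was 186 after the median shift, against 0 in the other 15 of 16 alternatives, and 10 of the 12 named trend genes then passed. With that shift the median of all genes in the pair lay at 0.58, against 0.04 after quantile normalization. The count of genes at least 2-fold apart in the pair, 874, was 346 without background correction, 562 with an offset of 50, 1817 after the median shift and 472 for genes detected on all 6 arrays, where fewer genes were counted. It was 2186 at 1.5-fold and 315 at 3-fold. Limma with the spread of the tamoxifen groups, in which the 2 lone arrays are assumed to vary like those, called 121 genes, and an added fit over genes of the 6-array filter called 31. Each probe on its own with probes of no listed gene included, 2 choices changed together and also added, gave 1867. The share of higher genes, 41.4%, was 28.3% without background correction and 83.5% after the median shift. Of the 12 list calls in the knockdown, 0 held in camera with an estimated correlation and 0 in fry (smallest adjusted p = 0.482 and 0.154). In the simulated data neither test called lists of 15 genes shifted by 0.3 and 0.6, and larger shifts or correlated genes were not simulated. With the preset correlation, 8 of the 12 lists passed in all 15 alternatives. The number of lists called ranged from 11 to 16 when 1 array was left out. The hair list ranged from -3.32 to 0.23 when 1 array was left out and turned above 0 without tamoxifen control replicate 2, and Srr to 0.36 without the probes of the shared profile, an added alternative, since another probe then stood for the gene. Ctnnb1 ranged from -0.286 to 0.0201 when 1 array was left out, turning above 0 without tamoxifen control replicate 2. In the stabilized array the medians of T and B cell markers, cell cycle genes and stress genes turned to 0.23, 0.38 and 0.13 after the median shift. The correlation between the models ranged from -0.235 to -0.0562 when 1 array was left out and was -0.318 over genes at least 2-fold apart in the knockdown. Where no cause is given for a change, the cause was not tested. With replicate number as a block, which the labels tie to no shared animal, litter or day, 0 genes passed in the knockdown in limma (smallest adjusted p = 0.111) and 15 lists were called. Deviations of same-numbered arrays from their group means correlated at 0.0385 over genes, so the numbers were not taken as pairs. That value covers all genes and cannot exclude a factor shared by same-numbered arrays in single lists. From replicate 1 to 2 the muscle list rose by 0.537 in the controls and 0.563 in the knockdown. Cell cycle medians fell in both, from 0.365 to -0.207 and from 0.0466 to -0.53. Hair medians went opposite ways, from -0.381 to 2.76 and from 0.397 to -0.896. Of 363 values of the 25 named knockdown genes under the alternatives, 361 kept their direction and their side of the threshold, and of 235 values of the 24 named genes of the pair 190 moved by less than the spread, 45 by more and 0 reversed. Apart from Ctnnb1, these genes were chosen from the same values for a small p or a large difference. None of the knockdown genes passed to begin with, so these counts are not an independent check. Probes near background limit the smallest differences that could be seen, since between 35.1% and 36.8% of probes were detected on an array.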

Other observations

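The comparisons and tests in this part were all chosen after the data had been seen.

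Wounds of the adenovirus model, whether control or stabilized, stood apart from the 4 wounds of the tamoxifen model in interferon response genes. All 20 measured genes of this list were higher on both adenovirus arrays than on every tamoxifen or knockdown array, with a median log2 difference of 1.52 that lay above all random lists. The largest differences were in the chemokine Cxcl10 (2.69), the antiviral GTPase Mx2 (2.67), the ubiquitin-like Isg15 (2.22) and the transcription factor Irf7 (2.03). Over all genes, both adenovirus arrays lay above all others in 13.3% and below all others in 16% of genes, where chance gives 6.67% in each direction. Differentiated epidermis genes (median -0.59, percentile 0) and adipocyte genes (median -0.75, percentile 0) were lower in the adenovirus model, and wound edge keratinocyte genes (median 0.64, percentile 100) and inflammatory cytokines (median 0.62, percentile 100) were higher. The medians of 23 of the 26 lists compared lay outside the middle 95% of random lists, so the interferon list stands out by its size and by holding for all its genes, not by differing. Among the others were skeletal muscle (-1.41) and Wnt target genes (-0.39). The models also differed in age, floxed exons and treatment, which these arrays do not separate.

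Single arrays carried their own signals. The number of probes at least 4-fold above all other arrays was 67 on tamoxifen control replicate 2, 52 on the GFP array, 15 on the stabilized array, 3 on knockdown replicate 2, and 0 on tamoxifen control replicate 1 and knockdown replicate 1. At least 4-fold below all other arrays were 11 probes on the stabilized array, 9 on the GFP array, 1 on knockdown replicate 1 and 0 on each of the others.

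The 9 probes at least 4-fold below all 5 other arrays on the GFP array were those for Fcer1g, Ifi205, Inmt, Adh1, Gusb, Fgfr1op2 and Tm7sf3, of which Fgfr1op2 and Tm7sf3 are next to each other with 0 protein-coding genes between them in GRCm38.p6. A sequence variant under the probe in that animal is a candidate explanation for Gusb and Fgfr1op2, whose other detected probes lay near the other arrays (median difference -0.426), although 1 of the 3 of Gusb was at -0.9998. A variant under 1 probe alone is argued against for Ifi205, Inmt and Adh1, where a second probe was dim as well (median -3.29). A further detected probe of Ifi205 was at -0.69. Variants under several probes of a gene would give the same values and were not tested. For Fcer1g, at -6.6 by its 1 detected probe, a sequence variant cannot be told apart from a true loss of the transcript, for want of a second probe. Fewer myeloid and mast cells are argued against for Fcer1g, since macrophage markers differed by a median of 0.178 and mast cell markers by 0.702, the latter in the direction this needs but far below the 6.07 of Fcer1g in the same comparison.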
